A study of Homo sapiens with 6 samples.

How the data were processed

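Gene expression was measured by RNA sequencing in 6 libraries of A375 cells, a human melanoma line grown in DMEM with fetal bovine serum. Of these, 3 carried a guide RNA against mCherry (control) and 3 a guide RNA against SOX10 (knockout), and each library was put in its group by its label. Total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit that selects polyadenylated RNA, per the labels' protocols. HISAT2 and HTSeq are named with the genome build hg38, per the submitters' processing notes. Their versions, the strand setting of the counting, the gene annotation release, the position of the guide and whether the knockout cells were a pool or a clone are not given in the sources used here. If the counting ignored strand, reads of overlapping and antisense genes cannot be told apart, and reads that match several near-identical genes may be discarded or split.

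The authors deposited raw read counts per gene, not normalized, in a table with a column per library. All 58721 gene identifiers of the table were those of GENCODE release 29 on the reference chromosomes, from which types and coordinates (GRCh38, the same assembly as hg38) were taken, and 58207 had a current gene symbol. No row was a counting summary, so reads outside genes are not part of the totals. Total counts were 71793584, 74745810 and 74970700 in control replicates 1, 2 and 3 and 70075002, 77390247 and 78148565 in knockout replicates 1, 2 and 3. A gene with 3 counts stood at 0.0384 to 0.0428 CPM, which was taken as the floor, and floors cover counting error only. Protein-coding genes held 95.9% to 96.3% of the counts, genes of the mitochondrial genome 0.526% to 0.870%. In all, 22071 genes had 0 counts in all libraries. Replicates of a group differed by more than sampling noise, and none was treated as a duplicate.

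Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (19263 genes), libraries were scaled by TMM, and knockout was compared with control by the two-sided quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes. Standard errors of log2 fold changes were derived from the same fit. The 32 gene lists were written from textbook knowledge before the data were examined, as were the tests, the rule for named genes and the alternatives. Each list was counted in the edgeR test, over all genes and adjusted over the list alone, and tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, two-sided, with adjustment over the 32 lists. SOX10 was also tested by an exact permutation of its log2 CPM.

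Genes were named by a rule: SOX10; a panel of 12 genes; the 6 genes with the largest increase and the 6 with the largest decrease among those past the threshold with a mean of at least 5 CPM, groups that did not overlap and an ordinary gene symbol; and for each list up to 2 further members with the smallest p past the threshold and 1 in the other direction, or the most abundant member where none passed. A gene that the rule takes is not reported here. Genes named outside this rule are said to be chosen after their values were seen.

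Alternatives were DESeq2 1.42.0, limma-voom, scaling by DESeq2 size factors or by total counts, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, a test against a 2-fold change (glmTreat), camera with an estimated correlation, and fry. Ranges of a list's adjusted p over 12 alternative fits leave out the replicate block, glmTreat, the estimated correlation and fry. For these p-values limma-voom, 1 of the 12, repeats the main test, since camera was run on the same voom values. Adjusted p-values that DESeq2 left missing were kept as missing. The procedure was tested on simulated counts of 19263 genes with the means and library sizes of this comparison, of which 200 were changed. It called 44 of 67 genes changed 1.5-fold (65.7%), 49 of 67 changed 2-fold (73.1%) and 66 of 66 changed 4-fold, and 12 of its 171 calls (7%) were unchanged genes. The simulation changed far fewer genes than the 28% past the threshold in the data. It also drew each library independently, without deviations shared between libraries of the same number. These shares therefore need not hold for the data. Further tables were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.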

Results

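RNA abundance was measured in A375, an established human melanoma cell line with a mutant BRAF gene, after CRISPR targeting. Guide RNAs were directed either at mCherry, a fluorescent protein gene that is not part of the human genome, or at SOX10, a transcription factor of the neural crest, melanocyte and glial lineages. There were 3 libraries with the mCherry guide, called control, and 3 SOX10 knockout libraries. Gene counts summed to between 70075002 (knockout replicate 1) and 78148565 (knockout replicate 3) per library, so that 3 counts corresponded to at most 0.0428 CPM, the usual count scaled to library size. Nothing in the labels says that replicates came from separate cultures, and p-values measure only the spread between these libraries, which may be technical. Values below are means ± SD of CPM over n = 3 libraries per group, written from control to knockout, and log2 fold changes are of knockout against control.

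The targeted gene was examined first. SOX10 (ENSG00000100146; GRCh38 chromosome 22, 37970686 to 37987422, minus strand) fell from 234 ± 9.36 to 45.5 ± 3.48 CPM, a log2 fold change of -2.36 with a standard error of 0.08 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.84e-07). The 3 knockout libraries held between 17.7% and 20.4% of the control mean, and all lay below every control library. An exact two-sided permutation test of the log2 CPM over the 20 assignments gave p = 0.1, the smallest that 3 against 3 libraries allow. The position of the guide within SOX10 is not given in the sources used here. SOX10 overlaps POLR2F on the opposite strand, and since the strand setting of the counting is not given, reads of the 2 genes may not be fully separated. POLR2F stood at 112.5 ± 25.2 CPM in control and 84.9 ± 16.6 CPM in knockout libraries and did not pass the test (log2 fold change -0.41, adjusted p = 0.139).

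The comparison asks which transcripts differ when SOX10 is targeted in this line. The largest increases among genes with a mean of at least 5 CPM included SOX9, a related transcription factor (ENSG00000125398; chromosome 17, 72121020 to 72126420), which rose from 2.00 ± 0.228 to 69.7 ± 7.02 CPM, 34.8-fold (log2 fold change 5.12, SE 0.12, edgeR adjusted p = 4.50e-08). RGS4, a regulator of G protein signalling, rose from 0.819 ± 0.154 to 26.97 ± 0.503 CPM; MMP3, a matrix metalloproteinase, from 0.880 ± 0.149 to 28.9 ± 1.20 CPM; and DIO2, the deiodinase that activates thyroid hormone, from 0.582 ± 0.0475 to 18.3 ± 0.780 CPM. ANXA10, an annexin, rose from 0.326 ± 0.102 to 11.6 ± 2.42 CPM, and IGFN1 rose from 0.189 ± 0.0940 to 13.7 ± 4.97 CPM. The largest decreases included RXRG, a retinoid X receptor (ENSG00000143171; chromosome 1, 165400917 to 165445355), which fell from 16.04 ± 0.909 to 0.215 ± 0.0440 CPM, 74.2-fold (log2 fold change -6.21, SE 0.14, edgeR adjusted p = 4.40e-08), and GAS7 from 243 ± 26.2 to 5.86 ± 0.440 CPM, 41.4-fold. MGAM2 fell from 20.6 ± 3.21 to 0.395 ± 0.192 CPM, the mucin gene MUC5B from 14.98 ± 3.52 to 0.318 ± 0.150 CPM, ARPP21 from 9.86 ± 0.906 to 0.229 ± 0.0908 CPM and the collagenase gene MMP8 from 17.2 ± 0.790 to 0.445 ± 0.0352 CPM. MMP8 (chromosome 11, 102711795 to 102727050) and MMP3 (chromosome 11, 102835801 to 102843803) lie in the same metalloproteinase cluster and went opposite ways. MGAM2 has a close paralog, MGAM, with which reads may be shared, and CCND1, SPRY4, TYMS, KIF20A, CDK6, FAS, HLA-DPA1, TNFAIP3, TIMP3, SOX6 and SQSTM1, named below, overlap other tested genes.

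Across the genome, 5396 of 19263 tested genes (28%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2694 higher and 2702 lower in knockout libraries (49.9% higher). Scaled by total counts alone, 3021 were higher and 2144 lower (58.5% higher). Of the 5396 genes, 1175 were at least 2-fold higher and 909 at least 2-fold lower. Over all tested genes, whether past the threshold or not, all knockout libraries lay on the same side of all control libraries in 8010 (41.6%), against 10% by chance. Among protein-coding genes 2217 were higher and 2379 lower of 13928 tested. The first principal component held 77.4% of the variance and separated the groups, and correlations of log2 CPM were at least 0.9916 within groups and at most 0.9667 between groups. Without knockout replicate 2 the number of lower genes was 1794; requiring at least 1 CPM in 3 libraries reduced the genes with a 2-fold or larger change to 661 higher and 578 lower, and a test against a 2-fold change (glmTreat) left 659 higher and 573 lower.

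**Figure D1:**
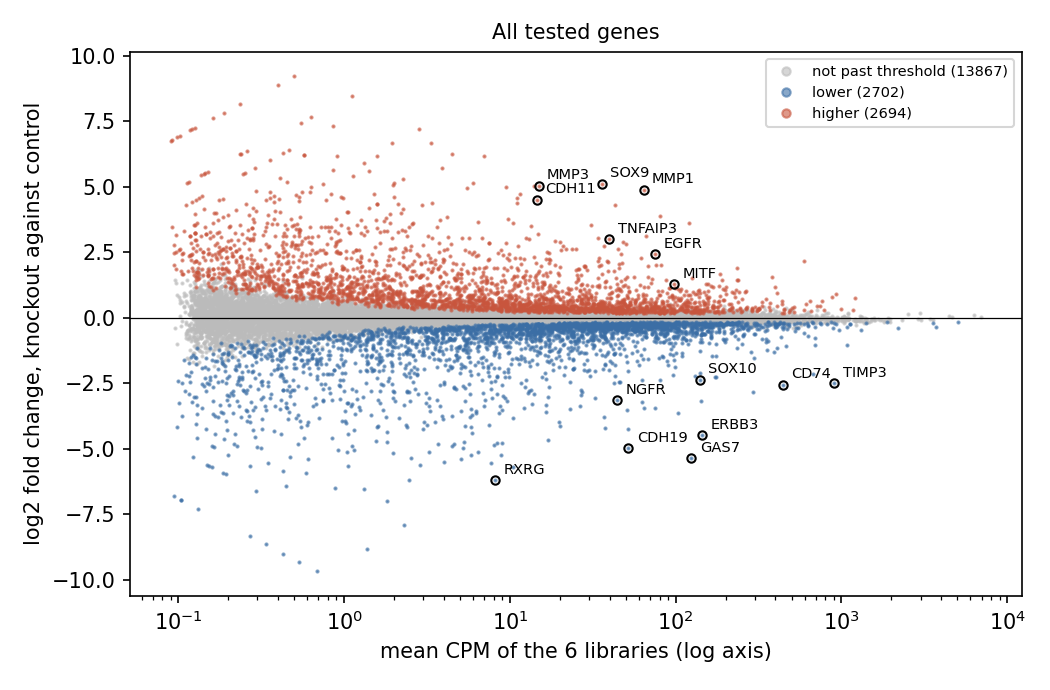
Log2 fold change of SOX10 knockout against control (vertical axis) against the mean CPM of the 6 libraries (horizontal log axis) for each of the 19263 tested genes, with 2694 genes past the threshold and higher and 2702 lower; circles mark genes named in the text. SOX10 lies at -2.36, SOX9 at 5.12, and RXRG at -6.21.

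Genes of the neural crest and of Schwann cells had the lowest median of the 32 gene lists. Of 25 tested members of this list, from which SOX10 was left out, 19 fell and 4 rose (19 and 5 adjusted over the list alone), with a median log2 fold change of -1.64. ERBB3, the neuregulin receptor (ENSG00000065361; chromosome 12, 56076799 to 56103505), fell from 276 ± 31.97 to 12.2 ± 1.52 CPM, 22.5-fold (log2 fold change -4.49, SE 0.13, edgeR adjusted p = 1.17e-07); the cadherin CDH19 fell from 100.4 ± 8.73 to 3.21 ± 0.252 CPM and the calcium-binding protein gene S100B from 32.9 ± 4.34 to 1.28 ± 0.134 CPM. GFRA1, a GDNF family receptor, rose from 0.718 ± 0.127 to 2.91 ± 0.497 CPM. The list stood below the other genes in camera (adjusted p = 1.00e-08; adjusted p = 0.134 with an estimated correlation).

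Other members of the SOX family also changed. Among the 11 tested SOX genes besides SOX10, 6 fell and 1, SOX9, rose, with the same counts adjusted over the list alone and a median of -0.84. SOX5 fell from 256 ± 15.3 to 92.7 ± 3.88 CPM and SOX6 from 3.33 ± 0.341 to 0.240 ± 0.0596 CPM, both of them SOXD genes. The list passed camera (adjusted p = 0.0236; adjusted p = 0.448 with an estimated correlation). Over 12 alternative fits the adjusted p ranged from 0.00932 to 0.0966, and it missed the threshold in DESeq2 (0.0654) and with at least 1 CPM required in 3 libraries (0.0966, with a median of -0.43).

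Melanocyte and pigment genes went both ways. MITF, the master regulator of the melanocyte lineage (ENSG00000187098; chromosome 3, 69739435 to 69968337), rose from 57.5 ± 2.15 to 138 ± 2.29 CPM, 2.40-fold (log2 fold change 1.27, SE 0.06, edgeR adjusted p = 9.86e-07), in knockout libraries. MLPH, which links pigment granules to myosin, rose from 2.90 ± 0.749 to 15.3 ± 0.398 CPM, whereas the pigment enzyme gene DCT fell from 1.62 ± 0.175 to 0.0657 ± 0.0258 CPM. In all, 7 of 16 tested members rose and 6 fell (7 and 7 adjusted over the list alone). The median log2 fold change was -0.14 and the mean 0.14, of opposite sign, and camera did not call the list (adjusted p = 0.939). Over 12 alternative fits the median ranged from -0.37 to 0.05, above 0 without knockout replicate 3.

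Genes of the dedifferentiated melanoma state that is marked by high AXL were mostly higher. Of 31 tested, 17 rose and 7 fell, with the same counts adjusted over the list alone and a median of 0.29. EGFR, the epidermal growth factor receptor, rose from 23.8 ± 3.78 to 127 ± 22.3 CPM, 5.35-fold (log2 fold change 2.42, SE 0.15, edgeR adjusted p = 6.99e-06), TGFBI, a matrix protein gene induced by TGF-beta, from 127 ± 6.32 to 347 ± 13.7 CPM, and AXL, a receptor kinase already abundant in control libraries, from 357 ± 16.3 to 516 ± 23.4 CPM. NGFR, the nerve growth factor receptor that also marks neural crest cells, fell from 79.8 ± 5.47 to 8.99 ± 0.0452 CPM, and the neural transcription factor gene POU3F2 from 47.8 ± 5.31 to 6.64 ± 0.734 CPM. PDGFRB stood at 5.91 ± 0.849 to 5.19 ± 0.309 CPM and did not pass the test (adjusted p = 0.296). Camera placed the list above the other genes (adjusted p = 0.0122; adjusted p = 0.640 with an estimated correlation).

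**Figure D2:**
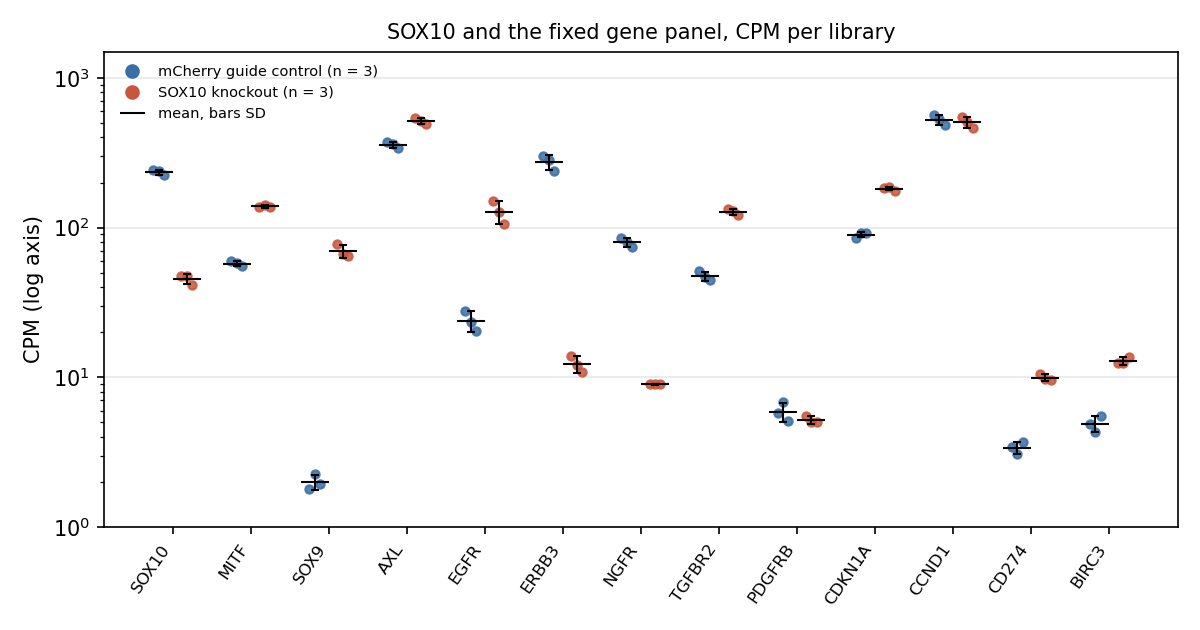
CPM on a log axis in each library for SOX10 and the panel of 12 genes fixed beforehand; points are the 3 control and 3 knockout libraries, horizontal marks the means and bars the SD. SOX9, EGFR and MITF lie higher and SOX10, ERBB3 and NGFR lower in every knockout library, while PDGFRB and CCND1 overlap.

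Receptor tyrosine kinase genes changed in both directions, more of them downward. Of 30 tested, 16 fell and 8 rose (18 and 8 adjusted over the list alone), with a median of -0.60. The VEGF receptor gene FLT1 fell from 30.1 ± 2.88 to 3.69 ± 0.315 CPM and the ephrin receptor gene EPHA3 from 141 ± 9.25 to 40.02 ± 0.513 CPM, while MET, the hepatocyte growth factor receptor, rose from 245 ± 21.4 to 552 ± 36.4 CPM. Camera called the list lower (adjusted p = 0.0129; adjusted p = 0.597 with an estimated correlation).

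Genes induced by MEK and ERK signalling were divided: of 24 tested, 10 fell and 6 rose (11 and 7 adjusted over the list alone). The feedback inhibitors SPRY2 and SPRY4 fell, SPRY2 from 159 ± 5.25 to 57.9 ± 0.439 CPM and SPRY4 from 117 ± 10.9 to 40.6 ± 2.92 CPM, while the phosphatase gene DUSP5 rose from 23.97 ± 0.639 to 41.03 ± 0.913 CPM. CCND1, the gene of cyclin D1, stood at 526 ± 42.8 to 504 ± 43.9 CPM and did not pass the test (adjusted p = 0.656). This list did not pass camera (median -0.10, adjusted p = 0.162). Over 12 alternative fits its median ranged from -0.17 to -0.03 and its adjusted p from 0.00450 to 0.236, past the threshold in DESeq2 (0.00450) and without a filter on low counts (0.0472). Among 15 tested AP-1 transcription factor genes, 7 rose and 4 fell (8 and 4 adjusted over the list alone). JUN rose from 13.8 ± 0.279 to 37.6 ± 1.44 CPM and MAF fell from 30.1 ± 1.87 to 3.01 ± 0.293 CPM. The median of the AP-1 list was 0.20 and camera did not call it (adjusted p = 0.205).

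More receptors and response genes of TGF-beta rose than fell. Of 25 tested, 16 rose and 3 fell, with the same counts adjusted over the list alone and a median of 0.45. TGFBR2, the type II receptor, rose from 47.5 ± 3.40 to 128 ± 6.07 CPM, 2.70-fold, and BAMBI, a decoy receptor that inhibits the pathway, fell from 26.4 ± 0.532 to 8.10 ± 0.448 CPM. Camera gave adjusted p = 1.26e-04 (adjusted p = 0.321 with an estimated correlation). Target genes of YAP, TAZ and TEAD were also higher, 13 of 24 rising and 4 falling (14 and 5 adjusted over the list alone), with a median of 0.39. The tissue factor gene F3 rose from 12.96 ± 1.08 to 45.2 ± 1.56 CPM, and IGFBP3, which binds insulin-like growth factors, fell from 48.2 ± 1.45 to 12.1 ± 1.49 CPM. The YAP list passed camera (adjusted p = 3.56e-04; adjusted p = 0.321 with an estimated correlation), and 2 tested genes stood in both this list and that of TGF-beta.

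Matrix and adhesion genes showed some of the widest changes without a common direction. The collagenase gene MMP1 (ENSG00000196611; chromosome 11, 102789920 to 102798160) rose from 4.18 ± 0.594 to 124 ± 13.2 CPM, 29.7-fold (log2 fold change 4.89, SE 0.13, edgeR adjusted p = 8.15e-08), while TIMP3, an inhibitor of metalloproteinases, fell from 1538 ± 76.9 to 274 ± 10.4 CPM, 5.60-fold. Of 41 tested matrix genes 18 rose and 8 fell (18 and 9 adjusted over the list alone). Their median was 0.04; camera did not call the list (adjusted p = 0.192), and over 12 alternative fits the median ranged from -0.06 to 0.15, on both sides of 0, and the adjusted p from 0.0300 to 0.471, past the threshold in DESeq2 alone (0.0300). Among 22 tested integrin and cadherin genes, 11 rose and 8 fell, with the same counts adjusted over the list alone (median 0.14, with 0.05 to 0.18 over 12 alternative fits, camera adjusted p = 0.354). CDH11, a mesenchymal cadherin, rose from 1.22 ± 0.272 to 27.8 ± 1.83 CPM, opposite to CDH19.

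Markers of other cell types moved in the same libraries. Of 15 tested fibroblast markers, 7 of which also stood in the matrix list, 9 rose and 2 fell (9 and 3 adjusted over the list alone). POSTN rose from 0.120 ± 0.0705 to 1.99 ± 0.0917 CPM and FAP from 0.353 ± 0.0568 to 2.11 ± 0.340 CPM, while TWIST1 fell from 12.4 ± 0.313 to 8.24 ± 0.299 CPM. The fibroblast median was 0.84 and camera did not call the list (adjusted p = 0.0818). Over 12 alternative fits the median ranged from 0.40 to 0.89, lowest with at least 1 CPM required in 3 libraries, and the adjusted p from 0.0168 to 0.248, past the threshold in DESeq2 (0.0168), without a filter on low counts (0.0209) and without knockout replicate 3 (0.0486). Keratinocyte and epithelial markers were higher, 7 of 13 rising and 1 falling (9 and 2 adjusted over the list alone), with a median of 0.48. KRT5 rose from 0.110 ± 0.00185 to 0.788 ± 0.0964 CPM, but its partner KRT14 fell from 7.16 ± 0.789 to 0.249 ± 0.0110 CPM. That list passed camera (adjusted p = 0.0158; adjusted p = 0.246 with an estimated correlation). Over 12 alternative fits its adjusted p ranged from 0.0158 to 0.305, and the call was lost in DESeq2 (0.305), with at least 1 CPM in 3 libraries (0.0784) and without knockout replicate 2 (0.0597). Keratin genes have close paralogs with which reads may be shared. Of 8 tested endothelial markers 2 rose and 3 fell, also adjusted over the list alone (median -0.23, with -0.57 to -0.10 over 12 alternative fits, camera adjusted p = 0.519); KDR, a VEGF receptor, fell from 6.32 ± 1.10 to 0.175 ± 0.128 CPM and CDH5 rose from 0.431 ± 0.121 to 1.96 ± 0.0580 CPM.

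Genes of DNA replication and of mitosis were lower as lists, by small amounts. For replication and the G1/S transition, 22 of 36 tested genes fell and the other 14 did not pass the test (27 fell, adjusted over the list alone), with a median of -0.30. The transcription factor gene E2F2 fell from 14.7 ± 0.196 to 8.52 ± 0.592 CPM and TYMS, which makes thymidylate, from 93.7 ± 8.32 to 58.4 ± 2.62 CPM. Camera gave adjusted p = 6.32e-08 (adjusted p = 0.146 with an estimated correlation). For G2/M and mitosis, 12 of 33 fell and the other 21 did not pass the test (18 fell, adjusted over the list alone), with a median of -0.24. The kinesin genes KIF20A and KIF11 fell, KIF20A from 208 ± 4.01 to 144 ± 1.23 CPM and KIF11 from 408 ± 16.1 to 287 ± 9.38 CPM, and the list passed camera (adjusted p = 1.75e-05; adjusted p = 0.168 with an estimated correlation).

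Regulators of the cell cycle changed singly. CDKN1A, the gene of the CDK inhibitor p21, rose from 89.9 ± 3.81 to 182 ± 5.19 CPM, 2.03-fold, whereas CDKN1C, the gene of the inhibitor p57, fell from 10.7 ± 0.456 to 0.957 ± 0.0225 CPM and CDK6 from 461 ± 53.7 to 240.4 ± 29.1 CPM. Of 14 tested CDK inhibitors, D cyclins and partners, 1 rose and 3 fell, with the same counts adjusted over the list alone (median -0.10, with -0.12 to -0.06 over 12 alternative fits, camera adjusted p = 0.183). Target genes of p53 were higher: 9 of 23 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.00791; adjusted p = 0.168 with an estimated correlation). GDF15, a stress-induced cytokine, rose from 3.11 ± 0.260 to 16.8 ± 0.755 CPM and the death receptor gene FAS from 29.4 ± 3.53 to 69.4 ± 8.70 CPM, while FAM210B fell from 62.1 ± 0.560 to 46.6 ± 0.752 CPM. In the BCL2 and IAP families 6 of 22 genes rose and 4 fell, with the same counts adjusted over the list alone (median -0.07, with -0.09 to 0.01 over 12 alternative fits, camera adjusted p = 0.939 with the sign of its statistic opposite to the median). BIRC3, an inhibitor of apoptosis, rose from 4.90 ± 0.604 to 12.9 ± 0.782 CPM, 2.62-fold, PMAIP1 rose from 37.3 ± 5.09 to 64.2 ± 7.55 CPM and BCL2A1 fell from 0.935 ± 0.0714 to 0.345 ± 0.0381 CPM.

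More antigen presentation genes fell than rose. MHC class II genes fell: HLA-DPA1 fell from 229 ± 3.44 to 52.6 ± 0.681 CPM, 4.36-fold, and CD74, the invariant chain of class II molecules (ENSG00000019582; chromosome 5, 150401637 to 150412929), from 758 ± 17.6 to 129 ± 7.73 CPM, 5.87-fold (log2 fold change -2.55, SE 0.07, edgeR adjusted p = 8.15e-08). CIITA, the regulator of class II transcription, fell from 57.9 ± 8.22 to 6.97 ± 1.29 CPM and HLA-DRA from 514 ± 96.3 to 71.1 ± 8.99 CPM. The class I gene HLA-B fell from 61.1 ± 5.81 to 23.3 ± 2.52 CPM, while NLRC5, the regulator of class I transcription, rose from 5.78 ± 0.375 to 9.44 ± 0.884 CPM. TAP1, a peptide transporter gene located within the class II region, stood at 18.2 ± 1.13 to 18.3 ± 0.894 CPM and did not pass the test (adjusted p = 0.972). CIITA, HLA-DRA, HLA-B and TAP1 were singled out after their values were seen, and reads of HLA genes may be shared between near-identical copies. Over the list, 15 of 29 tested genes fell and 5 rose (15 and 6 adjusted over the list alone), with a median of -0.40. Camera called it lower (adjusted p = 3.96e-04; adjusted p = 0.168 with an estimated correlation), with a median of -0.20 without knockout replicate 1 and -0.72 without knockout replicate 3. Blood cell markers, of which 4 of 16 were tested, moved in the same libraries without a common direction: LYZ fell from 12.2 ± 1.80 to 1.64 ± 0.360 CPM and CSF1R rose from 0.174 ± 0.107 to 0.748 ± 0.159 CPM (log2 fold change 2.09, and 2.68 without control replicate 1), the same 1 rise and 1 fall adjusted over the list alone. The blood cell median was 0.12 and the mean -0.14, of opposite sign (camera adjusted p = 0.939), and over 11 alternative fits that gave a value the median ranged from -0.41 to 0.50.

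**Figure D3:**
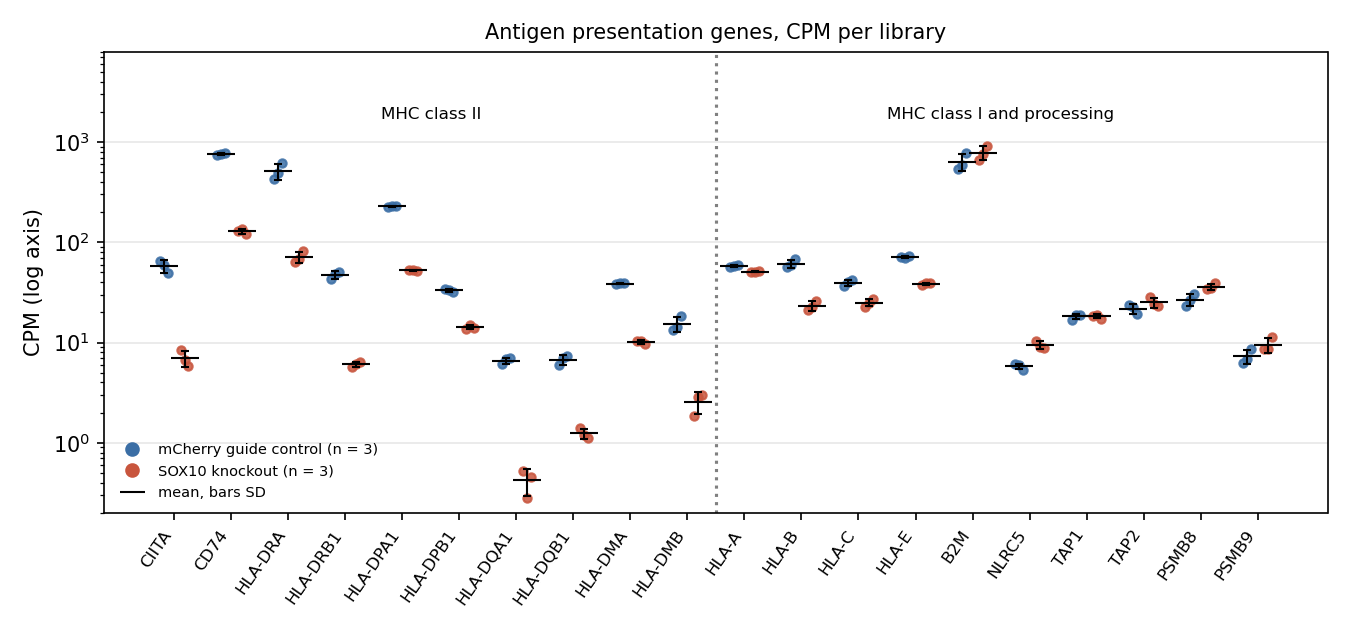
CPM on a log axis in each library for 20 antigen presentation genes, chosen after the values were seen; points are the 3 control and 3 knockout libraries, horizontal marks the means and bars the SD. The 10 class II genes left of the dotted line lie lower in every knockout library, and TAP1 on the right overlaps between groups.

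Interferon-stimulated genes were higher in the same libraries. Of 39 tested, 21 rose and 2 fell (21 and 4 adjusted over the list alone), with a median of 0.38. OASL rose from 0.399 ± 0.0622 to 4.05 ± 0.119 CPM, and GBP2, a guanylate-binding protein gene, fell from 11.5 ± 0.924 to 3.21 ± 0.373 CPM. Camera gave adjusted p = 8.15e-05 (adjusted p = 0.134 with an estimated correlation). CD274, the gene of the checkpoint ligand PD-L1, rose from 3.39 ± 0.322 to 9.96 ± 0.498 CPM, 2.93-fold. In the list of ligands that regulate T and NK cells, 10 of 22 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.22 (camera adjusted p = 0.0197; adjusted p = 0.168 with an estimated correlation). With at least 1 CPM required in 3 libraries the median was 0.35. NT5E, which makes adenosine, rose from 68.4 ± 1.84 to 146 ± 2.40 CPM, and NECTIN3 fell from 76.3 ± 1.49 to 40.4 ± 2.50 CPM.

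Inflammatory cytokines and chemokines rose in part. TNFAIP3, an NF-kappaB feedback inhibitor, rose from 8.79 ± 1.02 to 70.7 ± 5.82 CPM, 8.05-fold, and IL11 from 11.8 ± 1.85 to 45.4 ± 1.12 CPM, whereas IL1A fell from 3.68 ± 0.768 to 0.401 ± 0.0370 CPM. Of 26 tested, 12 rose and 4 fell (14 and 5 adjusted over the list alone); the median was 0.29, also with IL33, which had 0 counts in all control libraries, set to its bound. The list passed camera (adjusted p = 0.0136; adjusted p = 0.168 with an estimated correlation), but not with at least 1 CPM required in 3 libraries (median 0.19, adjusted p = 0.142, in a range from 0.00240 to 0.142 over 12 alternative fits).

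Cholesterol synthesis genes were lower as a list. Of 23 tested cholesterol synthesis genes 10 fell and 13 did not pass the test (11 fell and 1 rose, adjusted over the list alone), with a median of -0.27 (camera adjusted p = 9.37e-04; adjusted p = 0.168 with an estimated correlation). INSIG1, a regulator of sterol synthesis, fell from 32.7 ± 0.727 to 18.7 ± 0.885 CPM. Lysosome genes were higher, 13 of 33 rising and 20 not passing the test (13 rose and 1 fell, adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00851; adjusted p = 0.284 with an estimated correlation). The protease gene CTSK rose from 11.2 ± 0.793 to 24.7 ± 0.827 CPM and the autophagy receptor gene SQSTM1 from 189.7 ± 3.96 to 314 ± 8.84 CPM. For ATF4 and the unfolded protein response, 11 of 28 fell and 3 rose, with the same counts adjusted over the list alone and a median of -0.12, or -0.075 scaled by total counts alone. The cystine transporter gene SLC7A11 fell from 121 ± 1.55 to 43.8 ± 1.32 CPM and DDIT4 from 33.5 ± 3.00 to 15.04 ± 1.17 CPM, while ATF3 rose from 6.53 ± 1.29 to 16.6 ± 1.15 CPM. Camera called that list lower (adjusted p = 0.0180; adjusted p = 0.325 with an estimated correlation), except without knockout replicate 1 (adjusted p = 0.0587, in a range from 7.88e-04 to 0.0587 over 12 alternative fits).

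Respiratory chain, glycolysis and heat shock genes did not pass camera as lists. Of 33 tested genes of the respiratory chain and its regulation, 1 rose and 32 did not pass the test, also adjusted over the list alone: PPARGC1A, the coactivator of mitochondrial biogenesis, from 0.490 ± 0.0648 to 4.27 ± 0.306 CPM, 8.69-fold. The median was 0.04 (camera adjusted p = 0.186). Its median ranged from -0.02 to 0.16 over 12 alternative fits, on both sides of 0, and the adjusted p from 0.00366 to 0.836. Calls came without control replicate 3 (median 0.16, 0.00366) and without knockout replicate 1 (median 0.14, 0.0164). Of 27 glycolysis and hypoxia genes 5 rose and 8 fell, with the same counts adjusted over the list alone; the median was -0.05 and the mean 0.03, of opposite sign (camera adjusted p = 0.343), and over 12 alternative fits the median ranged from -0.10 to -0.01. ADM, the gene of adrenomedullin, rose from 12.3 ± 1.01 to 38.3 ± 1.92 CPM and MXI1 fell from 33.2 ± 0.543 to 16.5 ± 0.424 CPM. For heat shock and immediate early genes, 4 of 22 rose and 9 fell (4 and 11 adjusted over the list alone), NR4A1 from 24.6 ± 1.97 to 3.26 ± 0.116 CPM. Their median was -0.16 (camera adjusted p = 0.0805), and over 12 alternative fits the adjusted p ranged from 0.00600 to 0.157, past the threshold in DESeq2 (0.00600) and without a filter on low counts (0.0121).

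Ribosomal protein genes and genes of the mitochondrial genome did not pass as lists. By edgeR, 0 of 39 ribosomal protein genes and 0 of 13 genes of the mitochondrial genome passed, and the counts were 0 also at an unadjusted p under 0.05, adjusted over the list alone, in limma-voom and in DESeq2. RPS6, a protein of the small subunit, stood at 2923 ± 637 to 2839 ± 414 CPM and MT-CO1, a cytochrome oxidase subunit, at 1025 ± 244 to 1168 ± 214 CPM. The ribosomal list had a median of -0.04 and camera adjusted p = 0.489. That median ranged from -0.14 to 0.07 over 12 alternative fits, on both sides of 0, and the p from 0.0146 to 0.607, with calls without control replicate 1 (median -0.14, 0.0146) and without knockout replicate 3 (median -0.14, 0.0390). For the mitochondrial genome the median was 0.06 and camera adjusted p = 0.637. This median ranged from -0.15 to 0.28 over 12 alternative fits, on both sides of 0, and the p from 0.0311 to 0.997, with a call without control replicate 1 (median 0.28, 0.0311).

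Over the 32 lists, 17 passed camera with a preset correlation of 0.01 between genes, 9 higher and 8 lower. With the correlation estimated from these 6 libraries 0 did so, and 9 lists had an unadjusted p under 0.05. Splits of the libraries that mixed the groups, counted after the result was seen, each gave 2 to 12 lists past the threshold and 0 genes. In each of these splits both sides held control and knockout libraries in unequal numbers. The knockout difference was thus partly kept and partly added to the spread. Their counts cannot tell how many lists or genes would pass without that difference. Since the list calls depended on the setting of camera, a call of a list alone does not show an effect of the knockout. By fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, 25 lists passed.

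**Figure D4:**
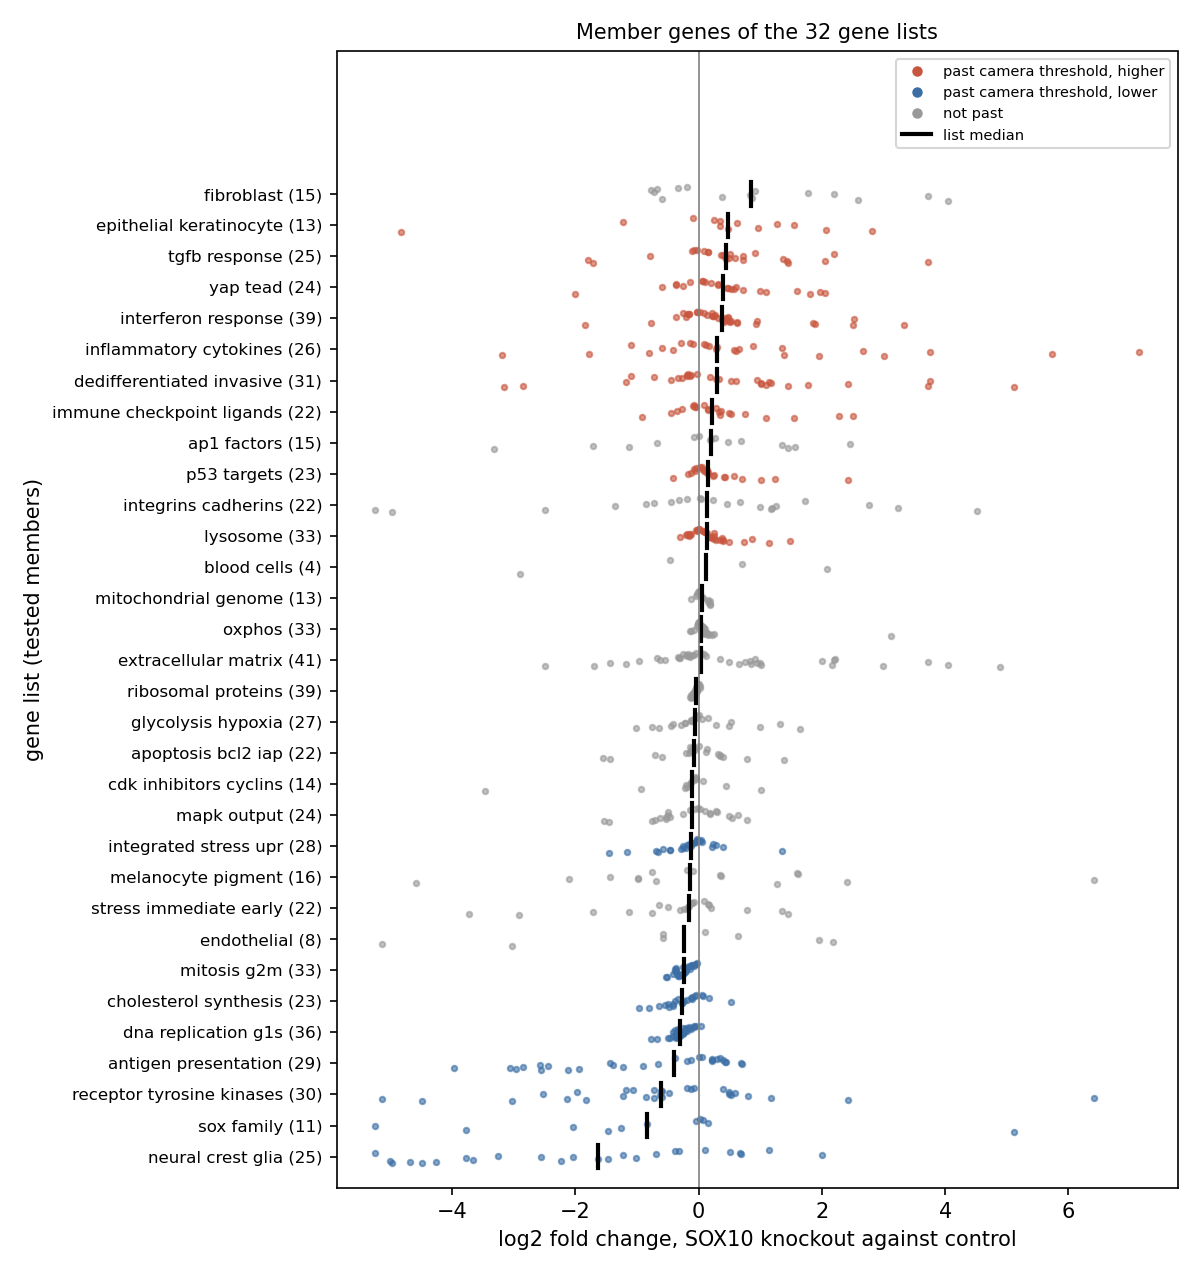
Log2 fold change of SOX10 knockout against control for each tested member (points, horizontal axis) of the 32 gene lists (rows, number of tested members in parentheses), with the list median as a black mark and colours for lists past camera. The neural crest and glia list has the lowest median, -1.64, and points of genes with almost no counts in 1 group, such as IL33 and KIT, depend on the prior count of the fit.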

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

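No alternative here was chosen after the result was seen. SOX10 stayed lower and past the threshold under each alternative that gave it a value, with log2 fold changes of -2.30 to -2.40. Of 1297 values of the other 100 genes taken by the naming rule or chosen later, under the alternatives, 1296 kept their direction and side of the threshold, and 1, MT-CO1 with the replicate block, came past it. Most of these genes were taken for a large change or a small p in the same data, so this does not speak for other genes. The genes past the threshold numbered 5576 in DESeq2, 5403 in limma-voom, 5312 with DESeq2 size factors, 5165 with total counts and 5357 without a filter on low counts, sharing 5112, 5336, 5250, 4838 and 4883 genes with the 5396. Leaving out single libraries gave 3797 (without control replicate 2) to 5893 (without control replicate 3) genes, and 1794 (without knockout replicate 2) to 2958 lower ones. With these fits, 3699 (without control replicate 2) to 4884 (without control replicate 3) of the 5396 genes were shared. The cause was not tested. Requiring 1 CPM in 3 libraries tested fewer genes and left 661 higher and 578 lower by 2-fold or more. A test against a 2-fold change, which asks for more than a change from 0, left 1232 genes, 659 higher and 573 lower. With the replicate number as a block, 9813 genes passed, 4637 higher and 5176 lower, of which 5389 were among the 5396. Deviations from the group means correlated at 0.302, -0.004 and 0.314 between libraries of the same number 1, 2 and 3. Number 2 missed the bound of 0.1 for every pair, and control replicate 2 correlated best with knockout replicate 1 (0.059). On the second principal component replicates 1, 2 and 3 stood at 24.2, 4.4 and -29.7 in control and at 23.9, -2.7 and -20.1 in knockout. Replicate 2 lay in the middle in both groups, so its correlation cannot decide whether the numbers pair the libraries. The block brought the respiratory chain list (adjusted p = 0.0198) and the ribosomal list (0.0380) past camera's threshold. With an estimated correlation 0 of the 17 lists passed. The estimate lay below the preset 0.01 for the interferon (0.004), p53 (-0.019), T and NK cell ligand (-0.026) and inflammatory cytokine (-0.01) lists. It lay above 0.01 for the others of the 17. A higher correlation among their own genes is thus not why the lists below 0.01 lost their calls, and the cause was not tested. The loss of calls under this setting can therefore not be read as an effect of the correlation alone. By fry the melanocyte and pigment list was called higher (adjusted p = 0.0315), reversed against camera, with its median still -0.143; the cause was not tested. Apart from these 2 settings, 4 lists lost and 7 gained a call under some alternative. Depth limits statements on genes near 3 counts per library.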

Other observations

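Among the tests below, those of gene families, non-coding genes, protein-coding windows with their interval and permutation, trends as the whole cause and MHC class II genes, and the counts over other splits, were chosen only after the result was seen, as were the genes named in the family tests. Families of protein-coding genes that share a symbol stem, at least 8 tested members each, were compared with all 13883 protein-coding genes considered, of which 16.0% rose and 17.1% fell (Fisher's exact test, two-sided, adjusted over 514 tests of 257 families; members of gene clusters are not independent). Interleukins and their receptors rose often, 17 of 42 (adjusted p = 0.0129), while 8 fell (19.0%). The median log2 fold change of this family was 0.028, so it did not shift one way as a whole. IL1RL1, the receptor of IL33, rose from 18.2 ± 1.88 to 221 ± 13.2 CPM, IL7R from 98.98 ± 4.79 to 372 ± 10.00 CPM and IL18 from 2.15 ± 0.256 to 24.6 ± 2.32 CPM, while IL16 fell from 2.04 ± 0.222 to 0.0564 ± 0.0128 CPM and IL1RAP, a coreceptor, from 44.7 ± 0.319 to 11.3 ± 1.12 CPM. Of 15 cadherin genes 9 rose (adjusted p = 0.0129) and 3 fell. CDH7 rose from 0.833 ± 0.0694 to 22.2 ± 0.217 CPM and CDH6 from 0.206 ± 0.0146 to 1.95 ± 0.412 CPM. Genes with the MMP stem, most of them matrix metalloproteinase genes but also MMP24OS, rose in 9 of 17 cases (adjusted p = 0.0247) and fell in 3. Keratin genes rose in 9 of 18 cases (adjusted p = 0.0380) and fell in 4. GAGE cancer-testis antigen genes, near-identical copies that share reads, rose in 9 of 11 cases (adjusted p = 4.61e-04) and fell in 0. HLA genes fell in 17 of 19 cases (adjusted p = 2.72e-09) and rose in 0. Guanine nucleotide exchange factors of the ARHGEF family fell in 11 of 22 (adjusted p = 0.0247) and rose in 5. Zinc finger genes of the ZNF family rose less often than other genes, 27 of 487 (adjusted p = 6.84e-10), while 64 fell, 13.1% (adjusted p = 0.206). Genes with the RPL stem, most of them of the large ribosomal subunit (48 tested, median log2 fold change -0.035), passed the threshold less often than other genes. That held in both directions (adjusted p = 0.0247 for rises and 0.0129 for falls). Genes of its mitochondrial counterpart (MRPL, 49 tested, median 0.073) were called lower less often (adjusted p = 0.0129). With the replicate number as a block the list of ribosomal proteins passed camera (adjusted p = 0.0380). Few calls therefore do not show that the RPL genes were unchanged.

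Long non-coding RNA genes that changed were more often higher than protein-coding ones that changed: of 2742 tested, 210 fell, and 64.1% of those past the threshold were higher against 48.3% (Fisher's exact test, two-sided, p = 4.57e-13). If strand was not used in counting, antisense genes share reads with their partners, so these counts are uncertain.

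MHC class II genes fell as a block: 12 of 13 class II HLA genes between HLA-DRA and HLA-DPB1 (GRCh38 chromosome 6, 32439842 to 33087201) were lower, with a median log2 fold change of -2.573. Loss of that region is argued against by the 5 other genes between them, TAP1, TAP2, PSMB8, PSMB9 and BRD2, whose median was 0.209. CD74 and CIITA, which lie on other chromosomes, also fell, with a log2 fold change of -2.553 for the one nearer to 0. The decrease is therefore not confined to reads of HLA copies. These 2 genes cannot show how reads were divided among the HLA copies, so the count of 12 of 13 may depend on shared reads. Loss of blood cells from control cultures is argued against by PTPRC, with 14 counts in control libraries against 165384 of CD74 (ratio 8.47e-05, upper 95% Poisson limit 0.000142). A candidate explanation left open, as a hypothesis, is the knockout itself by way of lower CIITA, the regulator of these genes, and no test here bears on that order. The decrease was also not confined to class II. The class I gene HLA-B fell too (log2 fold change -1.39), and of 19 HLA genes of both classes 17 fell and 0 rose. Whether CIITA bears on the class I genes was not tested. Whether the knockout cells were a pool or a clone is not given. Any other difference between the cells of the groups cannot be told apart from the knockout.

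Libraries numbered 1 and 3 differed in the same way in both groups: the log2 ratio of replicate 1 to replicate 3 correlated across genes, which are not independent, with a Spearman rho of 0.651 between control and knockout. Transcript length showed a trend in both groups (rho at least 0.35), which may be a technical part of it; for GC content the smaller rho was 0.146, between the bounds set, so it stays open. Neither trend is likely the whole cause, since the correlation stayed at 0.643 after medians of 20 GC bins and at 0.604 after medians of 20 length bins were removed. The labels do not say what the number marks, so no biological explanation was tested.

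Gain or loss of a large chromosome region could also move many genes together. The largest absolute median over 100 neighbouring tested genes was 0.215, on chromosome 9 (41073710 to 83538546), where 58 of the genes were not protein-coding; this lies just above the bound of 0.2 and below 0.3, so a gain or loss there stays open. Over protein-coding genes alone the largest was 0.167, on chromosome 5 (136975298 to 141641077), with a bootstrap 95% interval of 0.081 to 0.321 that reaches 0.3, so this stays open too. Under 1000 permutations of gene order the 95th percentile of the largest was 0.153 for all tested genes (p = 0.001, the smallest they can give) and 0.142 for protein-coding genes (p = 0.005), so neighbouring genes moved together beyond chance. Loss of chromosome 22 beyond SOX10 is argued against by a difference of -0.048 between the medians of 168 genes beyond and 257 before it (bootstrap 95% interval -0.101 to 0.033). The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 5396 genes and the highest other 0, and for the lists 17 and 12, with 1 split reaching the real value in each case. The other splits kept part of the knockout difference, so their counts are not those of libraries without it.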
